A study of Mus musculus with 2 samples.

How the data were processed

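RNA was measured by sequencing in 2 libraries of primary murine acute promyelocytic leukaemia (APL) cells, 1 library from each of 2 leukaemias called APL#1 and APL#2. Per the labels, leukaemic cells with the CD45.2 allele came from mice of the Ly5.2 strain and were injected into non-irradiated recipients carrying CD45.1. Per the labels, 2000000 cells were given for APL#1 and 200000 for APL#2, so the cell dose differs together with the leukaemia. CD45.2+ cells were then taken from the spleens and purified on immunomagnetic columns, and total RNA was sequenced with standard Illumina libraries, per the labels. The labels give an age of 10 weeks and no treatment for both samples, although both sample titles carry the letters VEH, which the labels do not explain. The labels also name the mice in 2 ways, as PML-RAR transgenic and as PML-RAR knock-in. The layout and strand of the reads, the annotation, the filters and the normalization setting are not given in the sources used here. The groups are the leukaemias named in the sample descriptions, with 1 library each.

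The authors deposited 1 gene table, and the submitters' processing notes name TopHat2 2.0.10, Cufflinks, Cuffdiff and mm9, with no role or order. The 2 value columns were read as FPKM (fragments scaled to transcript length and to the total of fragments), because the table deposited by the authors has the layout of a Cuffdiff gene table; its header names no unit. The FPKM values deposited by the authors were never negative and were not whole numbers, and they summed to 34893.9 for APL#1 and 35239.9 for APL#2. The deposited table also holds a test statistic, a score per gene from the authors' own test, per the file headers. It holds the authors' p-value and q-value per gene, per the file headers. The log2 column of the deposited table was not used, because it holds placeholder values where a library is at 0. No column in the table marks whether a gene passed the authors' checks for a test, so no gene was left out on that ground.

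The table holds 23235 genes, of which 9173 were at 0 in both libraries, 10322 in APL#1 and 9860 in APL#2. No gene symbol occurred more than once, and 89 rows carried several symbols. Differences were computed as log2((FPKM in APL#2 + 1)/(FPKM in APL#1 + 1)), with a pseudocount of 1, which understates the difference of low genes. The 4100 genes with a mean FPKM of at least 1 over both libraries are called measured below. A gene is called at least 2-fold higher or lower by this measure, so a low gene can have a plain ratio above 2 and not be counted. Folds given as numbers for single genes and for chromosome regions are plain ratios of FPKM; those of regions are medians over genes divided by the median ratio of all measured genes. With 1 library per leukaemia there is no replicate: no test was run, no p-value was computed, and no difference has a replicate check. A difference between the libraries can come from the leukaemia, the recipient, the cell dose or the library.

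Depth was estimated from low values. Among 3168 genes with mean FPKM under 0.2, the commonest ratio of APL#1 to APL#2 was 1.08, found within 0.1% in 304 genes, as for genes with equal numbers of fragments. Ratios of whole numbers up to 6 times that value covered 38.6% of the low genes. In 71 genes with 1 transcript, 1 fragment on a transcript of 1 kb was worth about 0.0194 FPKM in APL#1 and 0.0180 in APL#2, which implies scaling totals of about 51500000 and 55700000 fragments. On these estimates, FPKM 1 on a transcript of 2 kb stood for about 103 fragments in APL#1 and 111 in APL#2, with a counting error of 9.85% and 9.47%. The fragments assigned to the listed genes came to about 1690000 in APL#1 and 1680000 in APL#2, far below the scaling totals, for a reason not given in the sources used here. A second measure of error came from the deposited table: the ratio of each gene's log2 fold to the authors' test statistic, the standard error their test implies, had a median of 0.96 (log2) over measured genes and 0.72 over genes with mean FPKM of at least 5. That error rests on the authors' model of variability and not on replicates. It is wide beside the observed differences. Outside the chromosome blocks described below, the log2 ratios of 3693 genes, relative to the all-gene median, had an interquartile range of -0.28 to 0.25.

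Before the data were examined, 34 gene lists were fixed (20 pathway lists, 3 quality lists and 11 lists of cell type markers). They covered haematopoietic and leukaemia stem cells, Hox genes, a human stemness score, myeloid transcription factors, primary and later granules, retinoid signalling, LSD1 and CoREST, insulin and PI3K signalling, S phase, mitosis, oxidative phosphorylation, glycolysis, Myc targets, interferon response, unfolded protein response, p53 targets, the Bcl2 family, homing and adhesion, chromatin enzymes, immediate early genes, ribosomal proteins, sex-linked genes and other cell types of spleen. For each list with at least 5 measured members, the median difference minus the all-gene median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand outside when its percentile is under 2.5 or above 97.5, as a description of these libraries. In simulated data without a change, 7 of 100 lists of 17 genes stood outside, and 100 of 100 lists lowered by 0.5 did. The simulated lists held genes drawn at random, so these rates need not hold for lists whose genes vary together. The median of each chromosome and of runs of 50 neighbouring measured genes was computed in the same way. A search for stretches of at least 15 neighbouring genes that differ from the rest was added after the data had been seen. It compares each stretch with the highest value from 1000 shuffles of the gene order. In 20 simulations of a block of 70 genes lowered by 0.6, the block was found in 20, with its edge 2.6 genes off on average, and 1 further block was found. These simulations took their limit from 20 shuffles in place of 1000, a looser search.

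Named genes followed a rule fixed in advance. They are the 14 largest differences in each direction among 782 genes with 1 symbol and FPKM of at least 5 in a library, leaving out predicted genes, small RNA genes and immunoglobulin or T-cell receptor segments. Up to 4 measured members with the largest differences per list, the sex-linked genes, Ptprc, Rara, Pml, Kdm1a, Myc, Kit, Flt3 and Mpo were added. Genes outside the rule that are given with values were named after their values were seen, and so were Pmaip1, Bbc3 and the genes at the edges of the chromosome stretches. Coordinates are those of the deposited table on mm9, written from 1; a gene that overlaps others can carry the span of the whole cluster there. Alternatives fixed in advance were pseudocounts of 0.1 and 5, other minimum values, 3 rescalings, other fold limits, a stricter q-value, list means and 5 matching bins. Alternatives chosen after seeing the data were leaving out the chromosome blocks, leaving out small RNA genes, other settings of the block search, and a cubic fit on GC content, transcript length and mean expression. GC content and length came from GENCODE transcripts of GRCm38, matched by symbol for 99.1% of the measured genes; no coordinates were taken from that build. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.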

Results

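The data compare gene expression in 2 mouse acute promyelocytic leukaemias, APL#1 and APL#2, which the series describes as clones that differ in the frequency of leukaemia-initiating cells, the cells able to start the disease again in a new host. Which of the 2 has the higher frequency is not given in the sources used here. Acute promyelocytic leukaemia is a myeloid leukaemia driven by the PML-RAR fusion protein, in which cells accumulate at the promyelocyte stage of granulocyte development. Each leukaemia was represented by 1 library of CD45.2+ cells from spleen, so no difference below has a replicate check. About 1690000 fragments for APL#1 and 1680000 for APL#2 lay in the 23235 listed genes, as estimated from the low values. Of these genes, 4100 had a mean FPKM of at least 1.

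Expression was similar for most measured genes, and a limited set differed widely. Across the 4100 measured genes, log2(FPKM + 1) in the libraries correlated with Pearson's r of 0.83 and Spearman's rho of 0.77, across genes, which are not independent replicates. Differences of at least 2-fold on the log2(FPKM + 1) scale were found in 86 genes higher in APL#2 and 100 genes lower in APL#2. Genes of microRNAs and other small RNAs made up 33 of the 86 and 32 of the 100, and most of these were listed at 0 in one library (26 and 23 genes). Without small RNA genes the counts were 53 and 68. The median difference of all measured genes was -0.17, and differences of gene groups are given relative to it.

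After Xist, described with the sex-linked genes, the largest differences toward APL#2 were those of Sod3, Cd24a and Gsr. Sod3, the secreted superoxide dismutase, stood at 0.152 FPKM in APL#1 and 5.77 in APL#2. Gsr, glutathione reductase, stood at 9.13 and 47.3 FPKM, a 5.18-fold difference. Cd24a, a surface glycoprotein of immature blood cells, stood at 0.206 and 6.00 FPKM. The metallothioneins Mt1 (16.6 and 51.1 FPKM) and Mt2 (1.54 and 6.79) were 3.08-fold and 4.41-fold higher in APL#2. The basophil protease gene Mcpt8 was 7.90-fold higher, the calcium-binding protein gene S100a6 3.19-fold and the heat shock protein gene Hspa1b 4.02-fold; Hspa1b has a near-identical neighbour, Hspa1a, which was 2.46-fold higher, and reads may be split between them. H2-Q6, of the MHC class I family with close copies, was 2.88-fold higher and is likewise uncertain. Anxa1 (5.08 and 22.7 FPKM), Neat1 (1.43 and 7.21), Macrod1 (2.06 and 7.20) and Klrb1f (0.654 and 5.92) were also among the 14 largest, and these 4 lie in the chromosome regions described further on.

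Among the genes lower in APL#2, the largest differences with little doubt over close copies were those of Egr1, Elane and Cpa3, and Mpo had the highest level. Mpo, myeloperoxidase of the primary granules, stood at 661.8 FPKM in APL#1 and 157.3 in APL#2, a ratio of 4.21, and Elane, neutrophil elastase, at 32.4 and 5.01, a ratio of 6.46. Egr1, an immediate early transcription factor, stood at 49.4 and 5.19 FPKM, a ratio of 9.52. Cpa3, the mast cell carboxypeptidase, stood at 41.3 and 7.09 FPKM, and Hdc, which makes histamine, at 7.75 and 1.24. Thbs4, a secreted thrombospondin, stood at 46.7 and 10.2 FPKM. S100a8, a calcium-binding protein of granulocytes, was 2.93-fold higher in APL#1, with 309.0 and 105.3 FPKM. Xlr, an X-linked gene with close copies, stood at 12.9 FPKM in APL#1 and 0.0195 in APL#2. B2m, the light chain of MHC class I (91.8 and 28.8 FPKM), the ER disulphide isomerase gene Pdia3 (12.9 and 3.30), Slfn4 (10.9 and 3.02) and Lars2 (18.1 and 5.48) were 3.19-fold, 3.91-fold, 3.61-fold and 3.31-fold higher in APL#1. Atp6v0c-ps2, a pseudogene, and Rps27, a ribosomal protein gene with many pseudogenes, were also among the 14 largest but are uncertain, since the standard errors implied by the authors' deposited table were 2.38 and 18.5 on the log2 scale.

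**Figure D1:**
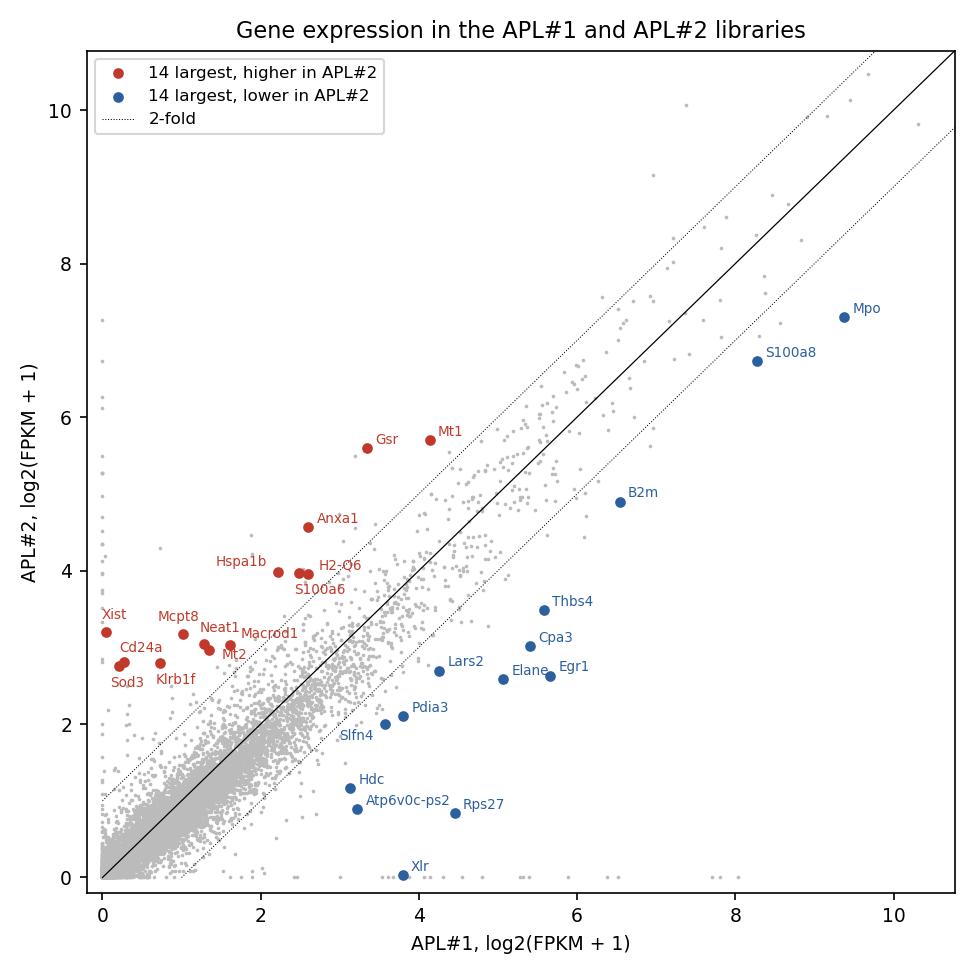
Each point is a gene, with log2(FPKM + 1) in APL#1 on the x axis and in APL#2 on the y axis; the solid line marks equal values and the dotted lines a 2-fold difference on this scale. The 14 genes with the largest differences in each direction under the naming rule are coloured and labelled, from Xist, Sod3 and Cd24a near the y axis to Xlr and Rps27 near the x axis.

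In the authors' deposited table, q was at most 0.05 for 11 genes, which compares these libraries and not replicated leukaemias. Of these, 6 were higher in APL#2 in the authors' deposited table: Xist (q 5.68e-07), Stag3 (2.48e-05), Sod3 (0.000979), Cd24a (0.00473), Gsr (0.0104) and Bmp3 (0.0280). The authors' deposited table gave 5 lower in APL#2: Egr1 (q 5.51e-05), Xlr (0.000207), Thbs4 (0.0164), Rnf43 (0.0318) and Akr1c12 (0.04996). Stag3 (0.0522 and 3.53 FPKM), Bmp3 (0.0241 and 1.12), Rnf43 (1.87 and 0.0630) and Akr1c12 (2.71 and 0.0630) fall outside the naming rule and were named after their values were seen. Mpo and Elane did not pass in the authors' deposited table (q 0.299 and 0.267), nor did Cpa3 (0.0640). The log2 fold of Gsr was 2.37 with an implied standard error of 0.53, and that of Mpo -2.07 with 0.61. The smallest log2 fold among the 11 genes was 2.20 in size. These folds and errors were computed here from the FPKM and test statistics in the authors' deposited table.

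Genes of protein folding in the endoplasmic reticulum were lower in APL#2 as a group. Of 17 measured unfolded protein response genes, 13 lay below the all-gene median and 4 were at least 2-fold lower on the log2(FPKM + 1) scale: Calr, calreticulin (119.9 and 48.1 FPKM), the chaperone gene Hspa5 (32.9 and 13.8), Pdia6 (8.20 and 2.95) and Sdf2l1 (12.9 and 5.38). None of the 17 was at least 2-fold higher. The list median lay 0.53 below that of all genes (log2 -0.53, percentile 0 among 10000 matched random lists). The transcription factor genes Xbp1 (6.49 and 5.66 FPKM), Atf4 (11.6 and 10.3) and Ddit3 (2.04 and 2.06), which act in this response, differed little in RNA level. RNA level does not measure the activity of these factors. Atf4 and Ddit3 were named after their values were seen.

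Cell cycle genes were lower in APL#2 as well. Of 17 measured genes of DNA replication and S phase, 14 lay below the all-gene median, with a list median of -0.34 relative to it (percentile 0.02). Pcna, the sliding clamp of DNA polymerase, stood at 10.3 FPKM in APL#1 and 3.74 in APL#2, Rrm2, of ribonucleotide reductase, at 4.64 and 1.84, Cdc45 at 3.29 and 1.30 and Mcm3 at 4.84 and 2.54. Pcna alone of the 17 was at least 2-fold lower on the log2(FPKM + 1) scale, and it lies in the chromosome 2 region described further on. Of 16 measured mitosis genes, 15 lay below the all-gene median, with a list median of -0.44 relative to it (percentile 0). The spindle checkpoint gene Mad2l1 (5.58 and 1.89 FPKM) and the ubiquitin-conjugating enzyme gene Ube2c (20.2 and 9.27) were at least 2-fold lower on the same scale, on which Aurkb (3.50 and 1.36) and Birc5 (4.86 and 2.11) came next.

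Oxidative phosphorylation genes were slightly lower in APL#2. Of 46 measured members, 37 lay below the all-gene median, and the list median was -0.25 relative to it (percentile 0.01). Ndufa1, a subunit of complex I, stood at 48.3 and 21.1 FPKM and was the 1 member at least 2-fold lower on the log2(FPKM + 1) scale; Ndufc1 stood at 3.08 and 1.15 and Ndufb5 at 2.68 and 0.956. Cox8a went the other way, at 26.5 and 50.5 FPKM, and lies on chromosome 19. With the mean over the list in place of the median, the list stood inside the range of random lists (percentile 2.94).

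Cytosolic ribosomal protein genes were higher in APL#2. Of 46 measured members, 44 lay above the all-gene median, by a median of 0.67 (log2; percentile 99.99). Rpl32 stood at 78.4 and 187.8 FPKM, Rpl23 at 20.5 and 39.3 and Rpl35 at 1.62 and 3.97, and Rpl32 was the 1 member at least 2-fold higher on the log2(FPKM + 1) scale. Rps27 (20.9 and 0.784 FPKM) and Rpl30 (1.84 and 1.21, named after its values were seen) lay below the all-gene median. These genes have many processed pseudogenes, so their levels are uncertain where reads were split. With the mean over the list in place of the median the list stood inside the range of random lists (percentile 96.45), and with Rps27 also left out, after the data were seen, it stood outside (percentile 98.65).

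A group of homing and adhesion genes and 2 short lists on cell survival stood above the all-gene median. Of 14 measured homing and adhesion genes, 9 lay above it, by a list median of 0.23 (percentile 99.23). Next to Cd24a, the adhesion receptor gene Vcam1 (3.94 and 7.47 FPKM) and the tetraspanin gene Cd9 (1.59 and 3.34) were higher in APL#2, whereas the integrin gene Itgal was at least 2-fold lower (4.58 and 1.60). Of 8 measured p53 target genes, 7 lay above the all-gene median, by a list median of 0.26 (percentile 97.67), with Perp (0.536 and 1.92 FPKM) and Cdkn1a (1.41 and 2.07) leading. All 7 measured Bcl2 family genes lay above the all-gene median, by a list median of 0.30 (percentile 98.49), but by little: Bcl2 stood at 0.926 and 1.18 FPKM, Mcl1 at 4.81 and 5.57, Bad at 0.953 and 1.17 and Bax at 7.18 and 6.42. Bax, Pmaip1 and Bbc3 are in both the p53 and the Bcl2 list. The p53 list stood outside the range of random lists in 6 of 12 settings and the Bcl2 list in 8 of 12, so neither is a firm difference.

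The other 11 lists with at least 5 measured members stood inside the range of random lists in the main setting, several with members that went both ways. Primary granule genes had a median of -0.01 relative to all genes (percentile 33.72): Elane, Mpo and Calr were at least 2-fold lower in APL#2, as was Prss57 (3.52 and 1.22 FPKM, named after its values were seen), and Calr is in the unfolded protein response list too, while the protease inhibitor gene Slpi was at least 2-fold higher (146.6 and 320.6). Later granule and neutrophil genes had a median of 0.16 (percentile 75.38). S100a8, S100a9 (378.8 and 148.1 FPKM) and Hp (61.2 and 32.3) were lower in APL#2, and Anxa1 was higher. Camp (97.55 and 152.5 FPKM), Ngp (31.7 and 41.7) and Olfm4 (2.16 and 4.37) were higher too, whereas Lcn2 (20.1 and 11.4) and Ltf (2.29 and 0.860) were lower. Adpgk (2.79 and 6.02 FPKM) was higher and is in the fixed list, but it encodes ADP-dependent glucokinase and not a granule protein. The 6 genes from Camp to Adpgk were named after their values were seen. Stem cell genes had a median of -0.23 (percentile 4.72) over 8 measured members, among them Egr1, Lmo2 (6.87 and 3.03 FPKM), Cd34 (7.52 and 4.40) and Gata2 (2.998 and 1.83). Immediate early genes had a median of -0.15 (percentile 11.95), with Dusp2 (4.01 and 0.686 FPKM) among 4 members at least 2-fold lower and Hspa1a and Hspa1b as those at least 2-fold higher. Myeloid transcription factors stood at 0.02 (percentile 69.48): Klf2 (5.07 and 9.73 FPKM) and Id1 (1.29 and 2.88) were higher in APL#2, and Cebpa (4.74 and 2.61) and Gfi1 (5.99 and 3.49) lower. Basophil, mast cell and eosinophil genes stood at -0.33 (percentile 3.23), with Cpa3 and Hdc lower and Mcpt8 higher.

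LSD1 and CoREST genes stood at 0.00 relative to all genes (percentile 47.58), with Hmg20b at 2.11 and 1.34 FPKM and Hdac1 at 2.54 and 1.84. Insulin and PI3K genes stood at 0.04 (percentile 60.38), with the receptor gene Igf1r at 0.585 and 1.53 FPKM, Eif4ebp1 at 2.34 and 3.68 and Akt1 at 3.50 and 2.22. Glycolysis genes stood at 0.03 (percentile 55.73), with Ldha at 9.16 and 5.29 FPKM and Hk2 at 0.870 and 1.70. Myc targets and ribosome biogenesis genes stood at 0.09 (percentile 92.46), with Nme1 at 3.99 and 1.72 FPKM and Cdk4 at 6.42 and 3.48. Histone and DNA modifying enzymes stood at 0.00 (percentile 48.35), with Idh2 at 3.96 and 1.92 FPKM and Ezh2 at 3.60 and 2.44. Of 15 lists with under 5 measured members, the Hoxa and Hoxb list had 1, Pbx2 (1.23 and 0.978 FPKM), the retinoid list had 2, Rara (7.20 and 8.65) and Rxrb (2.55 and 2.49), and the interferon list had 3, all under 2-fold. Of 4 measured genes of the human stemness score, Gpr56 (8.67 and 3.08 FPKM) was at least 2-fold lower in APL#2. Ptprc, which encodes CD45, stood at 4.66 and 4.10 FPKM, Pml at 0.664 and 0.729, Kdm1a, which encodes LSD1, at 0.715 and 0.794, Myc at 1.59 and 2.20, Kit at 1.46 and 1.26 and Flt3 at 0.00507 and 0.00937.

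**Figure D2:**
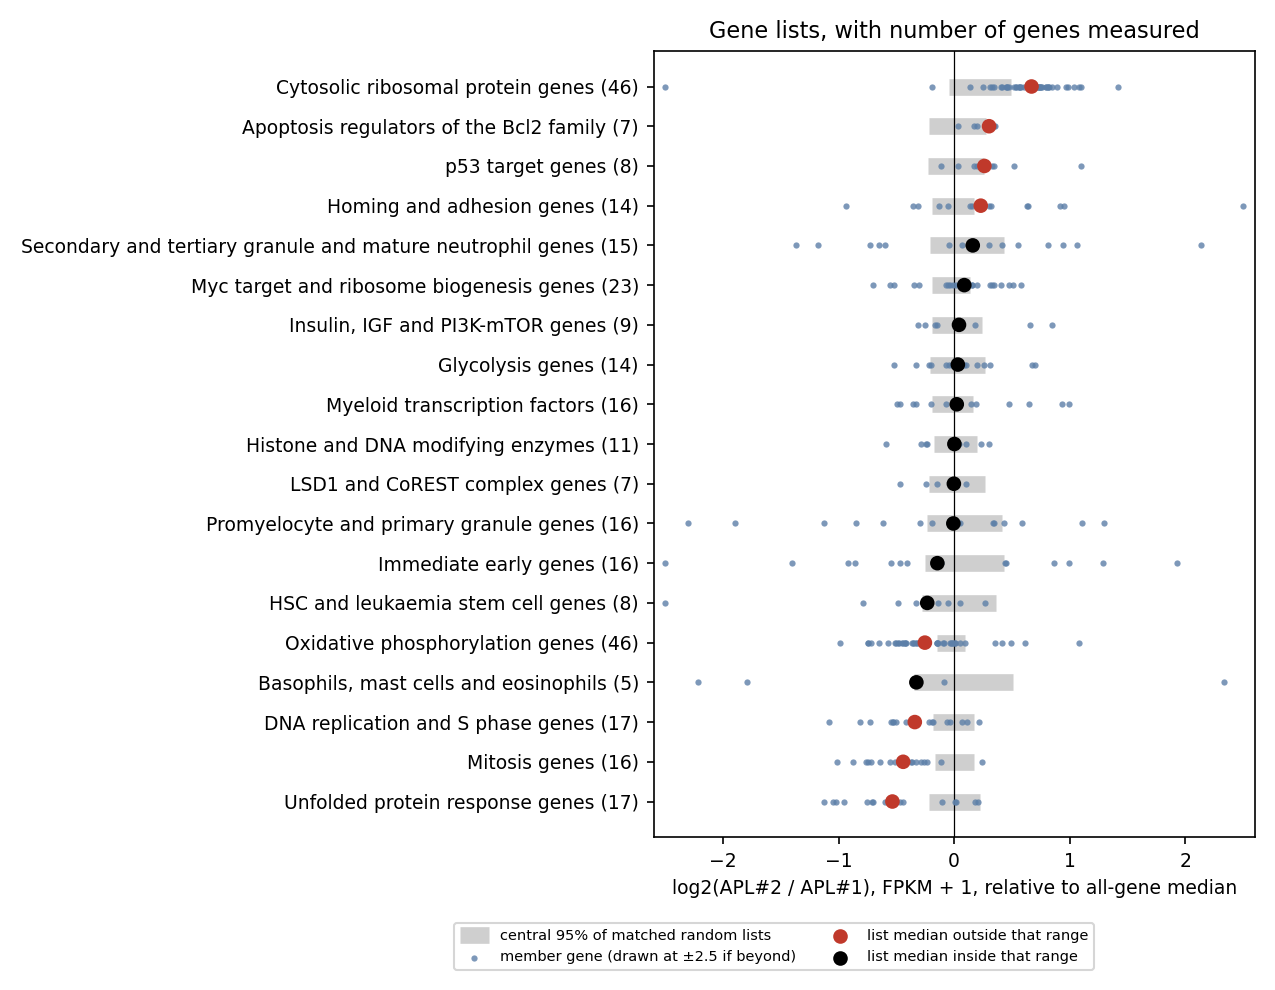
Each row is a gene list with its number of measured genes, and the x axis gives log2((FPKM in APL#2 + 1)/(FPKM in APL#1 + 1)) minus the all-gene median. Small points are genes, large points are list medians and grey bars span the central 95% of 10000 matched random lists; 4 list medians lie below their bar (unfolded protein response, mitosis, S phase and oxidative phosphorylation) and 4 above it.

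Differences also followed position in the genome: genes on 3 long stretches were shifted together. All of the measured part of chromosome 19 was higher in APL#2, with 134 genes from Ppp6r3 to Csf2ra (mm9 chromosome 19, 3454928 to 61304321), of which 133 lay above the all-gene median, at a median of 1.95-fold (interquartile range over genes 1.60 to 2.21). On chromosome 2, 72 genes from Psmd14 to 1110034G24Rik (mm9, 61549751 to 132576791) were lower in APL#2, with 71 below the all-gene median and a median of 0.517-fold (0.427 to 0.618), whereas the 203 measured genes on the rest of chromosome 2 stood at 0.987-fold. On chromosome 6, 153 genes from Capg to Far2 (mm9, 72494433 to 148392874) were higher, with 134 above the all-gene median and a median of 1.35-fold (1.17 to 1.68), and the other 81 genes of chromosome 6 stood at 1.05-fold. The search statistic was 16.0, -11.4 and 9.52 for chromosomes 19, 2 and 6, and its largest size in 1000 shuffles of gene order was 6.61. The other 17 chromosomes had medians between -0.06 and 0.06 (log2) relative to all genes. Chromosome 15 stood at 0.00 (percentile 57.56), chromosome 1 at 0.06 (percentile 99.60) and chromosome 7 at -0.05 (percentile 0.75), these last being the 2 that stood outside the range of random lists.

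Several genes named above lie in these stretches. The chromosome 2 stretch holds B2m, Pdia3, Hdc, Dusp2, Pcna, Nop56 (3.37 and 2.05 FPKM) and the stem cell factor Lmo2, as well as Sfpi1, which encodes the myeloid transcription factor PU.1 (8.55 and 5.74 FPKM) and was named after its values were seen. It held 14 of the 100 genes at least 2-fold lower in APL#2, and 1.76% of the measured genes. The stretches on chromosomes 6 and 19 held 19 of the 86 genes at least 2-fold higher (22.1%) and 7.0% of the measured genes. Among these 19 were Anxa1, Neat1 and Macrod1 on chromosome 19 and Klrb1f and Rpl32 on chromosome 6. The stretches were found from the same differences, so a raised share of such genes follows from the search and is no separate result. Gata2 lies in the chromosome 6 stretch and was lower in APL#2. With the genes of the 3 stretches left out, the unfolded protein response, S phase, mitosis, oxidative phosphorylation, ribosomal protein, homing and p53 lists stood outside the range of random lists as before, and the Bcl2 list did not (percentile 91.56).

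**Figure D3:**
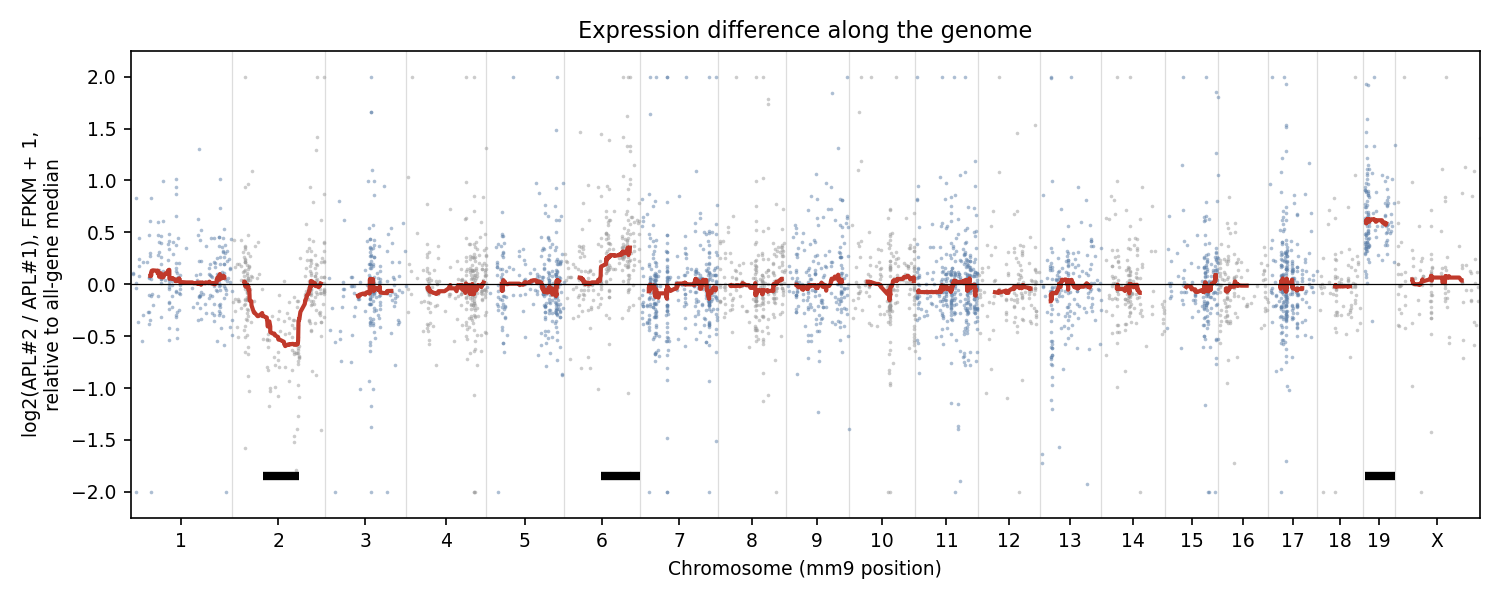
Points are the 4100 measured genes at their mm9 position along the chromosomes (x axis; chromosomes alternate in colour), with log2((FPKM in APL#2 + 1)/(FPKM in APL#1 + 1)) minus the all-gene median on the y axis, drawn at -2 or 2 if beyond. Red lines are medians of runs of 50 neighbouring genes and black bars mark the stretches on chromosomes 2, 6 and 19; run medians reach -0.60 on chromosome 2, 0.35 on chromosome 6 and 0.63 on chromosome 19.

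Sex-linked genes differed between the libraries. Xist, the RNA that silences an X chromosome in female cells, stood at 0.0319 FPKM in APL#1 and 8.20 in APL#2. The Y-linked genes Eif2s3y (2.06 FPKM), Ddx3y (0.749), Kdm5d (0.286) and Uty (0.275) had signal in APL#1; in APL#2 the first 3 were listed at 0 and Uty at 1.52e-05. Tsix, which overlaps Xist, and Usp9y were listed at 0 in both. The median of chromosome X stood at 0.04 relative to all genes (percentile 88.18).

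In each of the 11 lists of cell type markers, most genes were under FPKM 1 in both libraries, with exceptions in most lists. Of the measured marker genes, none belonged to erythroid, NK or dendritic cells, and the highest value of those lists was 0.694 FPKM for erythroid, 0.0259 for NK and 1.08 for dendritic cells (Cd74, 0.360 in APL#1, named after its values were seen). The B cell list had 1 measured gene, Cd37 (9.53 and 11.4 FPKM), the T cell list Tcf7 (1.05 and 1.73), the plasma cell list Xbp1 and the stroma list Pdgfrb (1.30 and 1.11). The macrophage list had Vcam1 and Cd68 (1.54 and 1.01 FPKM), and the megakaryocyte list Itga2b (2.34 and 3.95) and Plek (3.36 and 2.67). Monocyte genes, which immature myeloid cells also express, had 4 measured members: F13a1 was at least 2-fold lower in APL#2 (4.75 and 0.726 FPKM), Lyz2 stood at 20.1 and 11.2, Ly6c2 at 224.2 and 130.5 and Ms4a6c at 4.34 and 5.45. The basophil, mast cell and eosinophil list, given above, had Cpa3, Hdc and Mcpt8 among its measured members.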

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

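No paired analysis was possible because each leukaemia has 1 library. For the same reason no replicate could be left out. The settings with only genes marked as passing in the authors' checks, and with sums over repeated symbols, were not run, because the deposited table has no such mark and no repeated symbol. The alternatives without the chromosome blocks, without small RNA genes, with the fit on GC content, transcript length and expression, and with other settings of the block search were chosen after seeing the data. The unfolded protein response list kept its direction and stood outside the range of random lists in 13 of 13 settings. The mitosis, S phase and homing lists did so in 12 of 12, and the oxidative phosphorylation and ribosomal protein lists in 12 of 13. The main setting is included in these counts. So are the 3 rescalings, which multiply each library by a constant and could hardly move a list relative to genes rescaled alike. The fit on GC content, transcript length and expression accounted for 1.53% of the variance of the differences. The 11 lists inside the range gave 124 values under other settings, of which 2 stood outside: immediate early genes with no filter (percentile 1.41) and basophil, mast cell and eosinophil genes with a pseudocount of 0.1 (2.085). With a mean of at least 5, the S phase, mitosis, p53, Bcl2 and homing lists had under 5 genes and gave no value. Of the values of named genes under other settings, 597 moved by less than their implied standard error and 23 by more. This limit is lenient, because the implied errors are wide beside the observed interquartile range of -0.28 to 0.25 (log2) outside the chromosome blocks. The count of 597 therefore says little about stability. Genes at 0 in a library have no implied error and were set against a fixed value instead. The rescalings changed the ratio of the libraries by factors of 0.93 to 1.01, little beside most implied errors, so under them few values could have moved by more. The share of higher genes among those at least 2-fold apart was 46.2%, and 51.1%, 45.2% and 53.6% under the 3 rescalings; the median of all genes then moved from -0.17 to -0.13, -0.18 and -0.11. On depth, counting error alone was about 9.85% at FPKM 1 in APL#1 on a transcript of 2 kb. The median implied standard error of 0.96 (log2) is close to a 2-fold difference. It is wider than the observed interquartile range allows, so it need not be the error of a typical gene.

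Values that moved are grouped by setting; list and chromosome values are log2 relative to all genes. A pseudocount of 0.1 gave 132 genes higher and 252 lower, r of 0.73, and medians of -0.62 for mitosis, -0.70 for the unfolded protein response, 0.44 for the Bcl2 family, 0.34 for homing, -0.14, 0.33 and 0.91 for chromosomes 2, 6 and 19, and -0.90, 0.43 and 0.91 for their blocks. A pseudocount of 5 gave 48 and 45 genes, r of 0.87, and medians of -0.17 for S phase, -0.18 for mitosis, -0.13 for oxidative phosphorylation, -0.27 for the unfolded protein response, 0.10 for p53 targets, 0.12 for the Bcl2 family, 0.10 for homing, 0.53 for ribosomal proteins, and -0.039, 0.10 and 0.26 for chromosomes 2, 6 and 19. Both follow from the construction, since a pseudocount shrinks differences of low genes. No filter gave r of 0.94 and rho of 0.94, -0.42 for oxidative phosphorylation, -0.65 for the unfolded protein response, 0.022 for p53 targets, 0.031 for homing, 0.50 for ribosomal proteins, and 0, 0 and 0.020 for chromosomes 2, 6 and 19, with genes at 0 in both libraries setting the all-gene median at 0. The Bcl2 list reversed there, at -0.0010. A mean of at least 5 gave 46 and 65 genes among the 793 left, r of 0.62, rho of 0.62, -0.38 for oxidative phosphorylation, -0.87 for the unfolded protein response, and -0.22, 0.25 and 0.98 for chromosomes 2, 6 and 19. A mean of at least 2 gave blocks of -0.76, 0.35 and 0.76 on chromosomes 2, 6 and 19. A limit of 1.5-fold gave 225 and 416 genes and 4-fold gave 40 and 29. Without small RNA genes 53 were higher. List means gave 0.32 for homing and 0.53 for ribosomal proteins, and the fit on GC content gave 0.53 for ribosomal proteins. A q of at most 0.01 in the authors' deposited table left 2 lower genes. Where no construction is named, the cause was not tested.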

Other observations

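The lists of antioxidant genes and of endoplasmic reticulum genes, and the test of resting cells of other types, were chosen only after the results that prompted them had been seen, as were the chromosome block search and the fit on GC content. Genes named in this part and not in the naming rule were chosen after their values were seen. Genes for bringing proteins into the endoplasmic reticulum and attaching sugars to them were lower in APL#2. All 25 measured members of this list lay below the all-gene median, with a list median of -0.30 relative to it (percentile 0.03 among matched random lists) and a median fold of 0.735. The signal peptide translocation genes Sec61b (13.5 and 9.70 FPKM), Ssr2 (7.63 and 3.91) and Srp14 (4.15 and 1.57) and the oligosaccharyltransferase genes Ddost (15.1 and 7.30) and Rpn2 (11.6 and 5.23) are examples, and 2 of the 25, Rpn2 and Srp14, were at least 2-fold lower on the log2(FPKM + 1) scale. Without the chromosome blocks the percentile was 0.07, and after the fit on GC content, transcript length and expression it was 0.04. The hypothesis is that the lower expression of folding genes in APL#2 extends to the wider secretory machinery; the test could have come out the other way, but it used the same pair of libraries.

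Antioxidant genes as a group were not higher in APL#2, although Sod3 and Gsr were among the largest single differences and Mt1 and Mt2 were higher too. Of 18 measured members of a list of other antioxidant and NRF2 target genes, 11 lay above the all-gene median and 7 below, none differed by at least 2-fold on the log2(FPKM + 1) scale, and the list stood at percentile 72.495. Gpx1 (23.9 and 24.1 FPKM) was level, Tkt (15.6 and 10.2) and Sod1 (8.34 and 5.31) were lower in APL#2, and Prdx5 (16.8 and 30.9) and Fth1 (15.1 and 25.5), both on chromosome 19, were higher, as were G6pdx (1.37 and 2.44) and, below the measured range, Srxn1 (0.0147 and 0.204). The values argue against a shared antioxidant programme that takes in all of these genes.

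The chromosome blocks are the pattern most open to follow-up. A cubic fit on GC content, transcript length and expression kept at least 100.452% of each block's shift, which argues against such a bias as the whole cause. A difference in copy number between the leukaemias may account for them. Genes with mean FPKM of 0.1 to 0.5, not used to find the blocks, were shifted the same way in all 3, by at least 10.7542 SD of matched random lists. They stood at 0.528-fold in the chromosome 2 block, 1.96-fold in the chromosome 6 block and 1.90-fold on chromosome 19. Any other cause that acts on a whole region would shift its low genes too, so they cannot tell copy number apart from it. Over 5 ranges of expression the fold stayed between 0.460 and 0.536 on chromosome 2 and between 1.79 and 2.10 on chromosome 19, but on chromosome 6 it was 1.96 in these low genes, 1.46 at mean FPKM of 0.5 to 1 and 1.31 to 1.38 above that, a gap that a plain copy number difference does not predict and that stays open. The values show only a ratio, so neither the leukaemia that carries a change nor a change that both share can be read from them. No DNA data were analysed here. As background, loss of an interval of chromosome 2 that holds Sfpi1 is known from leukaemias of PML-RAR mice. Sfpi1 itself was shifted less (log2 difference -0.50 with the pseudocount of 1) than the median gene of the chromosome 2 block (-0.77).

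Ribosomal protein genes were higher in APL#2 by a median of 0.67 (log2), and after the fit on GC content, transcript length and expression the list stood at percentile 100 of matched random lists, which argues against that bias as the whole cause. Reads split between these genes and their many pseudogenes, and differences in RNA or library preparation, were not tested and stay open. A difference between the leukaemias stays open as well, since leukaemia, recipient, cell dose and library cannot be separated with 1 library each.

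Cell cycle and unfolded protein response genes were lower in APL#2 in the S phase, mitosis and unfolded protein response lists. With the genes inside the chromosome blocks left out, the highest percentile of the 3 lists was 0. It was again 0 after the fit on GC content, transcript length and expression. This argues against the list members inside the blocks, and against such a bias, as the whole cause. An effect of the blocks on genes elsewhere stays open, because only genes inside the blocks were left out. Resting B, T, NK, plasma, dendritic, erythroid, megakaryocyte, monocyte or macrophage cells in the APL#2 library would bring all their abundant transcripts. Over all members of the 9 marker lists fixed before the data were seen, the highest list median was 0.170% of Actb in APL#2 (monocytes, Actb 42.2 FPKM). This argues against a large share of those cells. The limit of 10% of Actb was set after the data were seen, and a list median can stay low where few members are strong markers. It decides least for monocytes, with 3 genes above the limit. Of the 138 genes in these lists, 6 stood above 10% of Actb in APL#2: Ly6c2 (495.5% in APL#1 and 309.1% in APL#2), Lyz2 (44.4% and 26.6%), Xbp1 (14.3% and 13.4%), Cd37 (21.1% and 26.9%), Ms4a6c (9.59% and 12.9%) and Vcam1 (8.70% and 17.7%). Resting basophils, mast cells, eosinophils, stromal cells and mature neutrophils share lists with other cells, so the 9 lists of this test leave them out. What their own mixed lists show is given next. The stroma and endothelium list had a median of 0% of Actb in both libraries, with 0 of its 17 genes above 10% in APL#2. These values argue against a large share of stromal cells. Of 28 later granule and neutrophil genes, 13 were under FPKM 1 in both libraries. Among these 13 were Cxcr2 (0.0924 and 0.0399 FPKM), Mmp8 (0.0156 and 0.0144) and Mmp9 (0.0894 and 0.0386). The highest of the 13 in APL#2 was Padi4 (0.129 and 0.272). These values argue against a large share of mature neutrophils that express these genes. Other members went both ways: Camp reached 152.5 in APL#2, whereas S100a8 and S100a9 were lower there. A small share of mature neutrophils stays open, as do basophils, mast cells and eosinophils. Mcpt8 stood at 2.2505% and 19.1% of Actb and Cpa3 at 91.3% and 16.8%. A biological difference between the leukaemias, including a lower share of dividing cells in APL#2, remains a hypothesis without a test in these data, and sex, shown by Xist and the Y-linked genes, differs between the libraries too.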
